A study of Rattus norvegicus with 4 samples.

How the data were processed

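Ribosome footprints were sequenced from cultured ventricular cardiomyocytes of newborn Wistar rats. Cells received a control siRNA or an siRNA against Cpeb4 for 72 h, with 2 libraries per group. Per the labels' protocols, polysome fractions from a sucrose gradient were digested with RNase I and the protected fragments were recovered for library preparation. The labels describe the libraries as ribosomal footprints but give polyA RNA as the molecule, and this difference is not resolved by the sources used here. The growth protocol also mentions pharmacological inhibition of mTORC1, a kinase complex that controls translation, without saying for which samples. It is therefore open whether these 4 libraries came from inhibitor-treated cells. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

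The deposited files hold raw read counts per Ensembl gene, with no normalisation, for 22250 genes. Per the submitters' processing notes, Bowtie2, STAR 2.7 and HTSeq 0.12 were used with the rat assembly Rnor_6.0. The notes do not give the role of each tool, and the strand setting of the counting is not given in the sources used here. The names of the deposited files state uniquely mapped reads of 29 to 34 nt in 3 libraries and of 29 to 33 nt in siCpeb4 replicate 2. Genes with near-identical copies, such as the muscle actins and ribosomal protein genes with processed pseudogenes, lose reads under unique mapping and are uncertain. Overlapping and antisense genes are uncertain as well. Gene symbols were taken from the files, and 99 symbols were shared by more than 1 gene. No coordinates are printed. Matched RNA-seq was not used here, so the values are footprint abundances and not translational efficiencies.

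Gene counts summed to 5863879 and 3554011 in control replicates 1 and 2, and to 4889212 and 5910911 in siCpeb4 replicates 1 and 2. The 5 HTSeq summary rows were left out of library sizes and tests. Reads without a feature made up 4.54%, 4.63%, 4.42% and 4.48% of the reads counted in these libraries, in the same order, and ambiguous reads made up 0.0916%, 0.0798%, 0.0877% and 0.0826%. The 20 most abundant genes took 16.0% to 17.1% of the counts. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 2.91 for the controls and 5.12 for the siCpeb4 libraries. This speaks only against 1 library deposited under 2 labels. It does not show separate cultures, since library preparation alone adds spread.

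The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3. It used TMM normalisation, a low-count filter (filterByExpr with a minimum count of 10), a model with the group as its only term, and Benjamini-Hochberg adjustment over 11335 genes tested. Tests were two-sided, and genes with an adjusted p under 0.05 were called. Standard errors (SE) of log2 fold changes were derived from the F statistic. Levels are CPM, counts scaled to a common library total, given as mean ± SD over the 2 libraries of a group. The biological coefficient of variation was 8.77%.

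Before the data were examined, 30 gene lists, the tests, the alternatives and the rule for named genes were fixed. The rule took Cpeb4, the other CPEB genes, Zeb1 and Zbtb20 whatever their values. It then took the 12 largest log2 fold changes in each direction among called genes with non-overlapping groups, skipping uncharacterised names. Last, it took up to 4 members per list with the smallest p. Col5a1, Col5a2, Rcan1, Tubb6 and Hyou1 are named beyond the rule to complete small counts, and Ankrd1, Nppa, Nppb and Myh7 to show uncalled members. Genes of the Zfp and Atp symbol families, apart from Zfp36l1 and Atp5pf, are beyond the rule as well. All of these were chosen after their values were seen. Some single-gene results are not reported here. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with adjustment over 25 lists. Counts of changed members are also given adjusted over the list alone. Alternatives were RLE and upper-quartile normalisation, DESeq2 1.42.0, limma-voom, robust edgeR, no low-count filter, at least 30 counts in 2 libraries, the replicate number as a block, each library left out, a threshold of 0.10, omission of the 20 most abundant genes, thinning to the smallest library, camera with an estimated correlation, and fry. With 1 library left out, the lone library of its group is assumed to vary like those of the other group.

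The workflow was tested on simulated counts for the siCpeb4 comparison, with 11335 genes and the real means and library sizes. It recovered 10.4% of genes changed 1.3-fold, 33.6% of those changed 1.5-fold, 82% of those changed 2-fold and 92.8% of those changed 3-fold. Of 575 calls, 15 were false. A simulated list shift of -0.3 was called in 5 of 5 runs. Genes were drawn independently, with dispersions that depended on expression level only. The simulation therefore cannot show how list calls behave when genes vary together, and the false calls hold for its setting only.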

Results

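Ribosome profiling was used to ask how a knockdown of Cpeb4 alters ribosome occupancy of mRNAs in isolated cardiac myocytes. CPEB4 is a cytoplasmic polyadenylation element binding protein, which binds elements in 3′ untranslated regions and regulates poly(A) tails and translation. The cells were ventricular cardiomyocytes of newborn rats, a primary culture widely used to study heart muscle growth. There were 2 libraries with control siRNA and 2 with Cpeb4 siRNA, each taken at 72 h. Footprints counted in genes ranged from 3554011 in control replicate 2 to 5910911 in siCpeb4 replicate 2. Log2 CPM values correlated across genes at r = 0.986 between the controls and 0.984 between the siCpeb4 libraries, against 0.978 to 0.981 between libraries of different groups.

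The targeted gene was the clearest change. Cpeb4 (ENSRNOG00000033169) had 351 and 253 counts in the control libraries and 40 and 59 in the siCpeb4 libraries. Its level was 66.3 ± 8.68 CPM (SD, n = 2) in controls and 8.99 ± 1.14 CPM (SD, n = 2) after siRNA, which is 86.2% lower in the fit. The log2 fold change was -2.86 ± 0.17 (SE), and it ranked 1 among all genes by p (edgeR adjusted p = 1.57e-09). Of the 3 CPEB family members tested, Cpeb3 rose 1.68-fold, from 24.6 ± 2.03 to 41.9 ± 6.42 CPM (edgeR adjusted p = 0.00919). Cpeb2 had a log2 fold change of 0.33 ± 0.16 and did not pass over all genes (edgeR adjusted p = 0.30). Adjusted over the list alone, 2 of these members rose and 1 fell. That list includes the siRNA target, and Cpeb2 kept its unadjusted edgeR p of 0.046 in it. Cpeb1 had 10 and 5 counts in controls and 3 and 15 after siRNA, too few to test. The Cpeb3 call ended in DESeq2 (adjusted p = 0.072) and without siCpeb4 replicate 1 (edgeR adjusted p = 0.084).

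Zeb1 and Zbtb20 are zinc finger transcription factors that the study ties to Cpeb4, so their direction here is not independent evidence. Zbtb20 rose 1.39-fold, from 98.7 ± 3.79 to 137 ± 15.4 CPM (SD, n = 2; edgeR adjusted p = 0.0227). Zeb1 had a log2 fold change of 0.44 ± 0.13 and did not pass (edgeR adjusted p = 0.0624). Adjusted over the list alone, 2 of the 2 rose, where Zeb1 kept its unadjusted edgeR p of 0.0024. The Zbtb20 call ended in DESeq2 (adjusted p = 0.066) and in edgeR without control replicate 1 (adjusted p = 0.22), control replicate 2 (0.065) or siCpeb4 replicate 1 (0.127). Zeb1 passed without control replicate 2 (edgeR adjusted p = 0.017), with robust edgeR (0.041), without the low-count filter (0.019) and with the replicate number as a block (0.044).

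Across the 11335 genes tested, 386 changed (edgeR, adjusted p under 0.05), of which 174 were higher and 212 lower after Cpeb4 siRNA. Most changes were modest. The log2 fold change was above 1 for 15 of the called genes and below -1 for 42, and 329 differed by less than 2-fold. In all 386 the libraries of the groups did not overlap. That held for 45.4% of all genes tested, where chance gives 33.3%. The count of calls was 186 in DESeq2 and fell to 212 without control replicate 1.

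The largest increases were seen in genes of varied function. Rnf2, the Polycomb ubiquitin ligase RING1B, rose 2.84-fold from 39.2 ± 3.22 to 112 ± 3.52 CPM (SD, n = 2; edgeR adjusted p = 1.96e-07). Golm1, a Golgi membrane protein, rose 2.41-fold to 117 ± 12.1 CPM, and Msrb3, a methionine sulfoxide reductase, rose 2.08-fold to 137 ± 6.1 CPM. Lrp8, a receptor for apolipoprotein E, rose 4.11-fold from 4.2 ± 1.09 to 18.0 ± 1.38 CPM. Xk rose 3.90-fold, the lysyl oxidase homologue Loxl4 3.65-fold and the DNA methyltransferase Dnmt3b 3.12-fold, from control levels of 2.35, 2.46 and 1.92 CPM. Wrb, part of the receptor that inserts tail-anchored proteins into the endoplasmic reticulum, rose 2.56-fold. Mycbpap (2.32-fold), Plppr5 (2.22-fold) and the tRNA queuosine enzyme subunit Qtrt2 (2.20-fold) followed. Pirt, a regulator of TRP channels, had 3 counts in the control libraries together and 26 in the siCpeb4 libraries. That ratio of 7.56 has an exact 95% interval of 2.32 to 39.0, which covers counting error only. Leaving out 1 library ended the calls of Pirt, Xk, Dnmt3b, Mycbpap and Qtrt2. Adjusted p reached 0.30 for Pirt without control replicate 2 and 0.20 for Qtrt2 without that library. Without control replicate 1 it was 0.16 for Xk, 0.40 for Dnmt3b and 0.60 for Mycbpap (all edgeR).

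The largest decreases after Cpeb4 itself were also in genes of varied function. Cd9, a tetraspanin, fell from 251 ± 17.5 to 97.0 ± 3.11 CPM (SD, n = 2), a log2 fold change of -1.37 ± 0.11 (edgeR adjusted p = 1.45e-07). Sdc4, the heparan sulfate proteoglycan syndecan 4, fell from 114 ± 2.44 to 41.4 ± 2.99 CPM (edgeR adjusted p = 1.96e-07), and Pip4p2, a phosphoinositide phosphatase, from 76.9 ± 0.155 to 28.2 ± 3.88 CPM. Hamp, which encodes the iron-regulating hormone hepcidin, fell from 61.1 ± 18.4 to 14.9 ± 4.03 CPM. Ppp2r2b, a regulatory subunit of protein phosphatase 2A, had the largest decrease apart from Cpeb4, with a log2 fold change of -2.62 ± 0.34. The complement component C6 (-1.97 ± 0.51), the axonemal dynein light chain Dnal1 (-1.63 ± 0.27), Plekha4 (-1.61 ± 0.34), the nucleotide hydrolase Hint1 (-1.52 ± 0.37) and the intraflagellar transport gene Ift74 (-1.44 ± 0.22) also fell. Reg3b, a secreted lectin, fell from 255 ± 87.0 to 85.7 ± 59.0 CPM, with a log2 fold change of -1.57 ± 0.27. Its replicates spread widely and its call ended with robust edgeR (adjusted p = 0.52) and in DESeq2 (adjusted p = 0.45). The calls of C6, Plekha4 and Hint1 ended in edgeR without control replicate 1, with adjusted p of 0.61, 0.22 and 0.43.

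**Figure D1:**
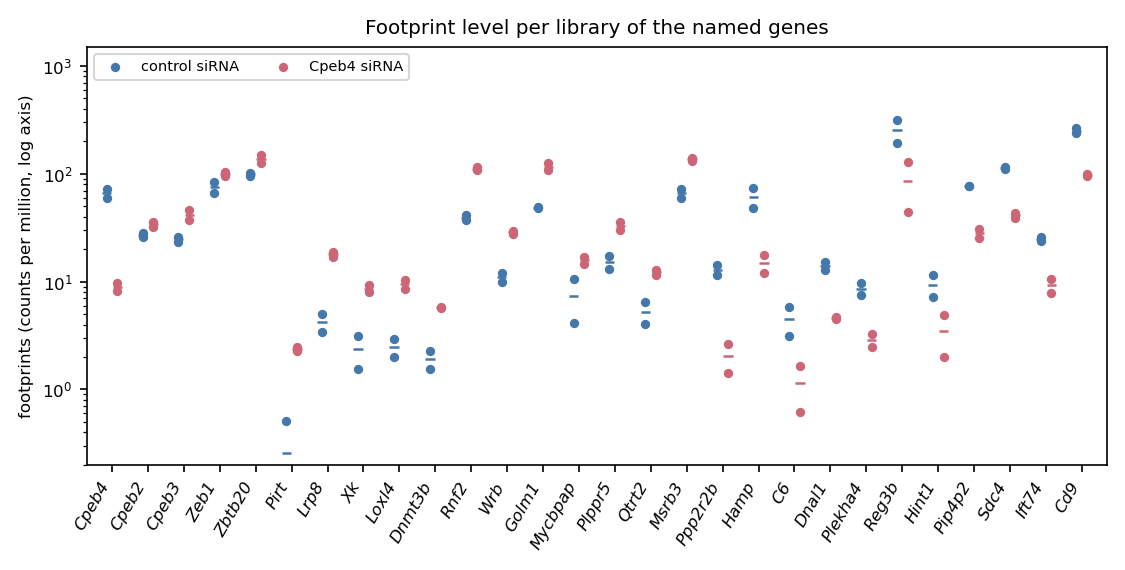
Footprint level in CPM (log axis) of Cpeb4, Cpeb2, Cpeb3, Zeb1, Zbtb20 and the genes with the largest called changes. Each point is a library, short lines are means of the 2 libraries per group, blue is control siRNA and red is Cpeb4 siRNA, and the control library with 0 Pirt counts cannot be drawn on the log axis. Cpeb4 lies at 66.3 CPM in controls and 8.99 CPM after siRNA.

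**Figure D2:**
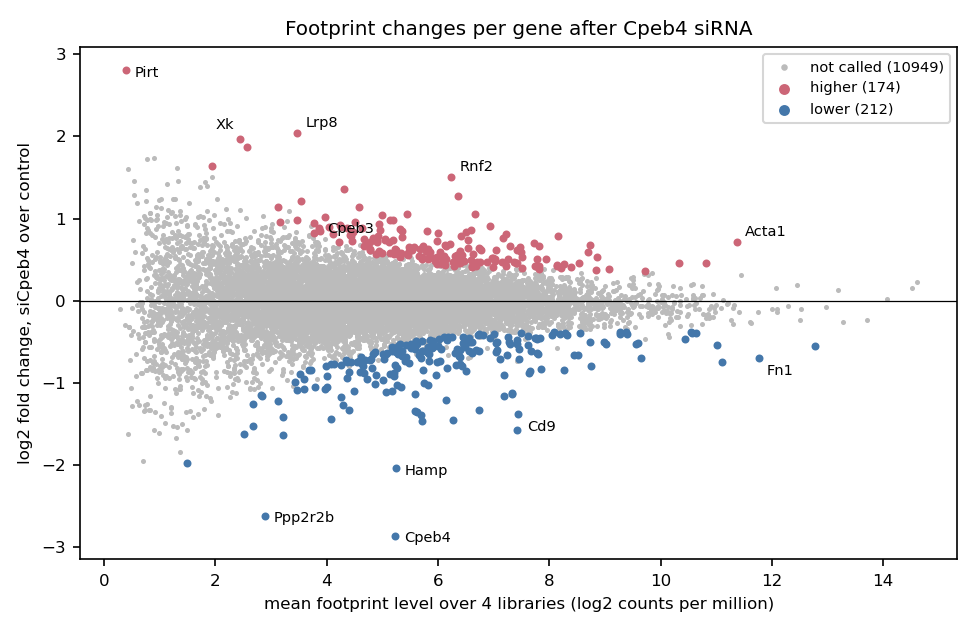
Log2 fold change of each of the 11335 genes tested (siCpeb4 over control, vertical axis) against its mean level over the 4 libraries (log2 CPM, horizontal axis). Red points are the 174 genes called higher, blue points the 212 called lower and grey points genes not called, and the called changes of abundant genes are small.

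Genes of the extracellular matrix and of fibroblasts were lower as a group after Cpeb4 siRNA. Of 30 members tested, 6 fell, none rose and 27 had a negative log2 fold change. Adjusted over the list alone, 13 fell. The matrix glycoprotein fibronectin, Fn1, fell from 4301 ± 400.4 to 2650.0 ± 411 CPM (SD, n = 2; edgeR adjusted p = 0.000687), and the calcification inhibitor Mgp from 993 ± 13.3 to 611 ± 28.9 CPM. Collagen Col1a1 had a log2 fold change of -0.55 ± 0.11 and Fbln2, a fibulin of the matrix, one of -0.66 ± 0.11, and Col5a1 (-0.41 ± 0.10) and Col5a2 (-0.37 ± 0.10) fell as well. The median of the list was -0.29 (camera adjusted p = 2.69e-09). That call is lost with an estimated correlation (adjusted p = 0.63). The Col1a1 call ended in edgeR without control replicate 1 (adjusted p = 0.055) or siCpeb4 replicate 2 (adjusted p = 0.094). Markers of other cell types had medians of -0.05 for 14 endothelial genes, -0.17 for 19 macrophage and leukocyte genes, -0.14 for 10 epicardial and mesothelial genes and -0.01 for 14 smooth muscle and pericyte genes. None of these lists passed (camera adjusted p = 0.55, 0.50, 0.42 and 0.87). The smooth muscle and pericyte list includes Des, which is also in the hypertrophy and fetal programme list, so it need not mark other cell types only. Without control replicate 2, the macrophage and leukocyte list had a median of -0.35 and passed (camera adjusted p = 0.00012), as it did without siCpeb4 replicate 2 (camera adjusted p = 0.04).

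The hypertrophy and fetal programme list had a median of -0.21 (camera adjusted p = 0.00615, and adjusted p = 0.67 with an estimated correlation). Of 22 members tested, 2 rose, 4 fell and 19 had a negative log2 fold change. The same counts of rises and falls passed adjusted over the list alone. The members that fell were the matrix protein tenascin C (Tnc, -0.66 ± 0.11), the matricellular growth factor Ccn2 (-0.53 ± 0.10), the metalloproteinase inhibitor Timp1 (-0.55 ± 0.14) and the tubulin Tubb6 (-0.39 ± 0.11). The skeletal actin Acta1, a classical fetal gene, rose from 2014 ± 338 to 3295 ± 335 CPM (SD, n = 2; edgeR adjusted p = 0.000687), and the calcineurin regulator Rcan1 had a log2 fold change of 0.42 ± 0.12. Acta1 is near-identical in coding sequence to the cardiac and smooth muscle actins, so its counts are uncertain. The list members Ankrd1 (-0.26 ± 0.11), Nppa (-0.05 ± 0.14), Nppb (-0.23 ± 0.18) and Myh7 (-0.24 ± 0.10) were not called. Of the called decreases, Tnc, Ccn2 and Timp1 are matrix-related genes, but most uncalled members were negative too. The list shift is thus not made by matrix-related genes alone. It still does not show a lower hypertrophy programme, since Acta1 and Rcan1 rose and the list call was lost with an estimated correlation. The list did not pass without siCpeb4 replicate 1 (camera adjusted p = 0.28), and without control replicate 1 the calls of Timp1 (edgeR adjusted p = 0.40) and Ccn2 (0.056) ended.

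Lists of ribosomal protein genes, of other mRNAs with a 5′ terminal oligopyrimidine tract and of respiration had slightly negative medians. Of 79 cytosolic ribosomal protein genes in the fixed list, 77 were found and only 43 passed the low-count filter. The values thus cover only part of the list. Those 43 had a median log2 fold change of -0.21, and 39 were negative (camera adjusted p = 0.000124, and adjusted p = 0.63 with an estimated correlation). None was called on its own by edgeR, by limma-voom or by DESeq2. In edgeR 13 had an unadjusted p under 0.05, as had 1824 of all 11335 genes tested. Rpl7 (-0.38 ± 0.11), Rpl30 (-0.72 ± 0.23) and Rpl4 (-0.30 ± 0.10) had small p. The list of translation factors and other genes whose mRNAs carry a 5′ terminal oligopyrimidine tract had 24 members tested and a median of -0.14. Its 1 called member was Cct7, a subunit of the chaperonin that folds cytosolic proteins and not a translation factor (-0.38 ± 0.10, edgeR adjusted p = 0.0373). In this list 3 members fell adjusted over the list alone. The list passed camera (adjusted p = 0.0101), not with an estimated correlation (adjusted p = 0.63), and not without control replicate 2 (median -0.08, camera adjusted p = 0.075). The Cct7 call ended when any one of the 4 libraries was left out, with edgeR adjusted p from 0.072 to 0.24. Of 46 nuclear-encoded genes of oxidative phosphorylation, the ATP synthase subunit Atp5pf (-0.50 ± 0.10) and the heart isoform of cytochrome oxidase subunit 6A, Cox6a2 (-0.47 ± 0.11), fell, 2 also adjusted over the list alone, and 40 members were negative. Their median was -0.10 (camera adjusted p = 0.0063, and adjusted p = 0.95 with an estimated correlation), but this shift rested on single libraries. The median was -0.04 without control replicate 2 (camera adjusted p = 0.34) and -0.02 without siCpeb4 replicate 2 (camera adjusted p = 0.44). Against the control mean, the list's median was -0.02 in siCpeb4 replicate 1 and -0.18 in siCpeb4 replicate 2, the library with the narrower footprint length window. The controls differed by a median of -0.12 (replicate 1 minus replicate 2), a larger difference than the shift between groups. Without control replicate 2, edgeR adjusted p was 0.12 for Atp5pf and 0.23 for Cox6a2.

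In other lists, members moved in both directions. Among 23 endoplasmic reticulum chaperone and quality control genes, the ubiquitin ligase adaptor Sel1l rose 1.58-fold from 138 ± 7.93 to 218 ± 1.62 CPM (SD, n = 2; edgeR adjusted p = 0.000679). The chaperones Dnajb9 (0.56 ± 0.12) and Hyou1 (0.37 ± 0.10) rose too, whereas Edem1 (-0.64 ± 0.15) and Derl1 (-0.54 ± 0.14), which act in degradation of misfolded proteins, fell. Adjusted over the list alone, 4 rose and 3 fell. The list did not pass (median 0.13, camera adjusted p = 0.0535), but did without control replicate 1 (camera adjusted p = 0.0186) or siCpeb4 replicate 1 (0.0171), with no low-count filter (0.037) and with upper-quartile scaling (0.044). Among 42 RNA-binding and 3′ UTR regulators, Zfp36l1, which promotes decay of AU-rich mRNAs, rose 1.88-fold from 85.0 ± 4.09 to 160 ± 9.74 CPM (edgeR adjusted p = 3.64e-05). The splicing regulator Rbfox2 (0.46 ± 0.11) and the antiproliferative protein Tob1 (0.48 ± 0.12) rose, and the deadenylase Cnot6l fell (-0.76 ± 0.14). The same 3 and 1 passed adjusted over the list alone, and the median was 0.10 (camera adjusted p = 0.10, and 0.035 without control replicate 2 or 0.026 without siCpeb4 replicate 1). The calls of Sel1l, Zfp36l1 and Cnot6l held with each library left out. In edgeR the adjusted p was 0.49 for Edem1, 0.25 for Rbfox2 and 0.35 for Tob1 without control replicate 1, 0.15 for Derl1 without control replicate 2 and 0.084 for Dnajb9 without siCpeb4 replicate 2.

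Metabolic and excitability genes were split as well. Of 20 glycolysis genes, the glucose transporter Slc2a1 (0.47 ± 0.11) and hexokinase Hk2 (0.48 ± 0.13) rose and the muscle enolase Eno3 fell (-0.82 ± 0.17). Of 24 calcium handling and excitability genes, the L-type calcium channel Cacna1c (0.41 ± 0.10) and the potassium channel Kcnj2 (0.50 ± 0.13) rose, and sarcolipin, Sln (-0.73 ± 0.19), and S100a1 (-0.49 ± 0.13) fell. Of 27 fatty acid oxidation genes, 1 rose, the dehydrogenase Hadh (0.71 ± 0.13). Of 27 sarcomere genes, Nexn rose (0.36 ± 0.10) and Nebl fell (-0.53 ± 0.10). Of 19 inflammatory genes, the adhesion molecules Vcam1 (0.54 ± 0.15) and Icam1 (-0.51 ± 0.14) changed in opposite directions. Of 30 interferon response genes, Mx1 was at the threshold (0.56 ± 0.16) and Ifi44 fell (-0.96 ± 0.17). Of the 14 genes in the smooth muscle and pericyte list, Abcc9 rose (0.40 ± 0.11). The 20 regulators of epithelial-mesenchymal transition had a median of -0.03 (camera adjusted p = 0.77). Adjusted over the list alone, the numbers higher and lower were 2 and 3 for glycolysis, 2 and 3 for calcium handling, 2 and 0 for fatty acid oxidation and 1 and 2 for the sarcomere. They were 1 and 3 for inflammatory, 3 and 1 for interferon and 1 and 0 for smooth muscle genes. None of these 8 lists passed camera (lowest adjusted p = 0.165). The inflammatory list passed without control replicate 2 (camera adjusted p = 6.9e-05) or siCpeb4 replicate 2 (0.00025), and the interferon list without control replicate 1 (1.6e-05). The calls of Hadh and Ifi44 held with each library left out. Each other gene named here lost its call without at least 1 library, with the highest edgeR adjusted p between 0.064 for Nebl and 0.44 for Kcnj2. The smooth muscle list has a median of -0.01 and an unweighted mean of 0.03.

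No gene passed in edgeR in 10 further lists, which hold 220 tested members. They cover cardiac transcription factors, the integrated stress response, cell cycle, cholesterol synthesis, autophagy and lysosome, p53 targets, immediate early genes, and the endothelial, leukocyte and epicardial markers. Among these members 20 had an unadjusted p under 0.05 in edgeR, as had 1824 of all 11335 genes tested. From the same members limma-voom called 2 and DESeq2 called 1. Adjusted over the list alone, 2 cardiac transcription factors were higher and 1 epicardial marker was lower. Tbx20 had the smallest p of the former (0.34 ± 0.10, edgeR adjusted p = 0.0563). Medians of these lists lay between -0.17 and 0.05. For cardiac transcription factors, the integrated stress response and autophagy the median was positive and the mean just below 0. Without siCpeb4 replicate 2 the cell cycle and cholesterol lists passed (camera adjusted p = 0.043 and 0.012), the latter also without control replicate 2 (0.037). Among lists too small to test, the 3 tested Schwann cell and neuron markers and the 1 tested erythroid marker, Hbb, did not pass, and no mitochondrially encoded gene was found under the names used.

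**Figure D3:**
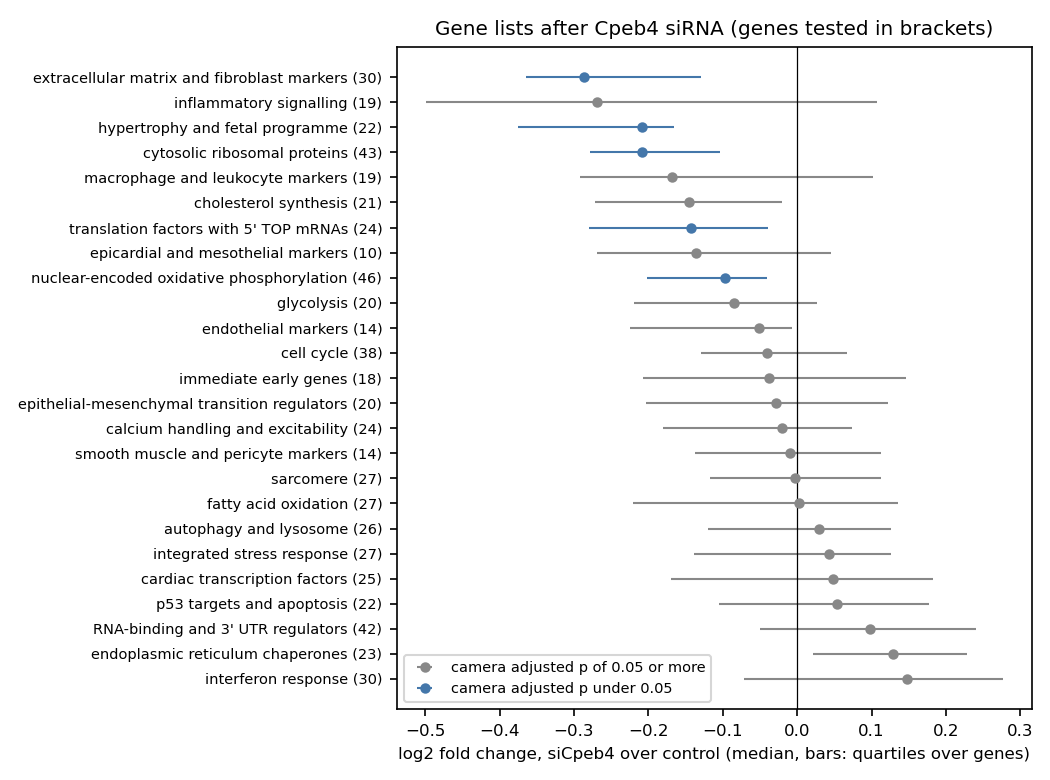
Median log2 fold change (siCpeb4 over control, horizontal axis) of the 25 gene lists tested, with the number of genes tested in brackets. Points are medians over genes, bars are quartiles over genes, and blue marks the 5 lists with a camera adjusted p under 0.05, all with negative medians.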

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

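None of the 60 called genes besides Cpeb4 taken by the naming rule and followed through the alternatives changed direction where it was tested. No called list did so either. For the genes this outcome was largely fixed in advance, because groups did not overlap in any of the 386 called genes. Leaving out a library could hardly reverse such genes. Under TMM, RLE and upper-quartile scaling the median of all genes lay between -0.005 and 0.011. Called log2 fold changes were at least 0.359 in size in the main test. The unchanged gene directions are thus no real test. Directions of the other called genes were not followed. Medians of some uncalled lists crossed 0, such as the inflammatory list (-0.405 to 0.022). Cpeb4 stayed called throughout, with log2 fold changes from -3.07 to -2.73. The count of changed genes was 606 without the low-count filter (352 lower), 629 at an adjusted p under 0.10 (274 higher, 355 lower) and 186 in DESeq2 (75 higher, 111 lower). Of the DESeq2 calls, 183 were shared with edgeR in the same direction. With each library left out in turn, 212 to 318 genes were called, 79 to 133 higher and 133 to 185 lower. Causes of these shifts were not tested, beyond the looser threshold, the added genes and the fewer libraries themselves. Other settings gave 327 to 481 calls.

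The 5 shifted lists became 6 to 8 with 1 library left out, 8 without siCpeb4 replicate 2. With an estimated correlation camera called 0 lists and fry 0, although 1 and 3 had an unadjusted p under 0.05. With 25 lists and 2 libraries per group, the list calls rest on the preset correlation.

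The labels do not say that equal replicate numbers pair libraries, and deviations of same-numbered libraries correlated at -0.109. The replicate block gave 403 calls (179 higher, 224 lower). Crossed pairing, chosen after seeing the data, gave 481 (202 higher, 279 lower). Of the named genes called, DESeq2 lost 14 of the 48 with an adjusted p, and leaving out control replicate 1 lost 26 of 60. At these depths and with 2 libraries per group, 10.4% of simulated 1.3-fold changes were recovered. The share of this limit that is due to depth was not tested, and thinning each library to the smallest total left 327 calls.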

Other observations

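The grouping of genes by the start of their symbol and the comparison with markers of other cell types were chosen only after the results were seen. Of 134 families of at least 10 tested genes, 4 had a camera adjusted p under 0.05, and 0 did with an estimated correlation (adjusted p = 0.99 for each of the 4). Besides Zfp and Atp these were Col (26 genes, median -0.26, camera adjusted p = 0.0049) and Rpl (30 genes, median -0.21, camera adjusted p = 0.032), which overlap the matrix and ribosomal protein lists. The 206 genes named Zfp, which are mostly zinc finger proteins, had a median log2 fold change of 0.16, and 149 were positive (camera adjusted p = 0.0041, and adjusted p = 0.99 with an estimated correlation). In edgeR 5 of them were called, all higher. They were Zfp36l1, Zfp516, Zfp574, Zfp319 and Zfp871, with log2 fold changes of 0.91, 0.69, 0.56, 0.60 and 0.45. None of 10000 random lists matched on mean expression had a median as high. The family was picked from these same fold changes, and the draws ignore correlation between genes. They therefore add no independent support. The family did not pass without control replicate 1 (camera adjusted p = 0.077).

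The 59 genes named Atp, most of them ATPase or ATP synthase subunits, had a median of -0.12 (camera adjusted p = 0.0041, and adjusted p = 0.99 with an estimated correlation). The camera call held without each library in turn, and 0.07% of expression-matched random lists had a median as low. This family too was picked from the same fold changes, so those draws add no independent support. In edgeR 6 were called, all lower. The vacuolar proton pump genes Atp6v1e1 and Atp6ap1 fell by 0.91 ± 0.11 and 0.84 ± 0.10 (SE) on the log2 scale, and the sodium pump subunit Atp1b1 by 0.51 ± 0.10. Atp5pf (-0.50) and Atp8b1 (-0.75) were also among them. These genes were named after their values were seen. Both family directions held under TMM, RLE and upper-quartile scaling. The median of all genes lay between -0.005 and 0.011 under these scalings. Such shifts could hardly turn medians of 0.16 and -0.12, so this was no real test of the families.

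The lower extracellular matrix and fibroblast list could come from a smaller share of contaminating cells in the cultures. A loss of all non-myocytes alike would lower other markers as much as the matrix list. Means weighted by inverse variance over genes were compared, and that of the matrix list was -0.296. The endothelial markers had a weighted mean of -0.0831 (95% interval -0.181 to 0.015). Weighted means were -0.081 for leukocyte, -0.126 for epicardial and -0.009 for smooth muscle markers. Unweighted means were -0.285 for the matrix list, -0.135 for endothelial, -0.103 for leukocyte, -0.122 for epicardial and 0.034 for smooth muscle markers. The smooth muscle list includes Des, also a member of the hypertrophy list, so it need not measure contaminating cells. All were less negative than the matrix mean. That order was partly fixed in advance, since the matrix list had the lowest median of the 25 lists tested and the comparison was chosen afterwards. The order may also depend on single libraries, as the leukocyte median moved from -0.17 to -0.35 without control replicate 2. These values therefore do not decide whether all non-myocytes were lost alike. The endothelial interval also treats genes from the same 4 libraries as independent, so it is too narrow to exclude an equal loss. A smaller share of fibroblasts alone cannot be told apart from a change of expression in them, such as an effect of the Cpeb4 siRNA. The 8 tested of 9 markers taken as fibroblast-restricted had a weighted mean of -0.279. Thy1 (0.21 ± 0.22) and Tcf21 (0.10 ± 0.19) were positive, but no marker had a 95% interval wholly above -0.1. Whether these markers are restricted to fibroblasts was not tested here. Their Cochran Q gave p = 0.0253 against a chi-square distribution, an approximation that leans on SEs from 2 libraries per group.

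The lower ribosomal protein list was set against 3 technical explanations. A narrower footprint length window was used in siCpeb4 replicate 2, but the list was lower in siCpeb4 replicate 1 as well, with a median of -0.145 against the control mean, compared with -0.272 in replicate 2. Expression level alone is argued against, since 0 of 10000 expression-matched lists had a median as low. Those draws ignore correlation between genes, so they cannot tell the shift from joint variation of the list's genes between libraries. The shift did not rest on 1 control library, because its median was still -0.177 without the control library that moved it most. Such joint variation stays open, since the list did not pass with an estimated correlation (camera adjusted p = 0.63) or with fry (adjusted p = 0.40). Reads shared with pseudogenes, inhibition of mTORC1 and an effect of Cpeb4 stay open and untested.

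Library depth is an unlikely source of the changed genes as a whole, since 327 genes were called with each library thinned to the smallest total, against 386 before. Whether the changes follow polyadenylation elements in 3′ untranslated regions, or matches to the siRNA seed, was not analysed here.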
